A study of Mus musculus with 21 samples.

How the data were processed

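The study measured total RNA of the whole right lung of A/J, C57BL/6 and C3H/HeJ mice on 21 mouse Affymetrix arrays of 22690 probe sets, from control mice and from mice given bleomycin by osmotic minipump. Per the labels, RNA was extracted with Trizol, pooled over several mice per array and processed with standard Affymetrix procedures. The deposited values were intensity on a linear scale, at least 0, with 1 decimal. The software that summarised probes, its background correction and its scaling are not given in the sources used here. Array medians differed by a ratio of 1.90, so the deposited values had not been brought to 1 level. No pair of arrays held identical values. The ratio of the 3′ to the 5′ Gapdh control probe sets, which rises with RNA degradation, ran from 0.770 to 2.08 and was highest on the C3H/HeJ female 6 week array.

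All 21 columns of the table matched a sample. The 64 control probe sets were left out, which left 22626. Gene symbols came from the array annotation and were brought to current symbols through a gene table, which matched 20364 of the 20380 probe sets with exactly 1 symbol; 691 carried several symbols and 1555 none. Values were quantile normalized between arrays, since medians differed by more than 1.2 times, and turned into log2 of the value plus 16. The dimmest 33.3 percent of the probe sets by mean over all arrays were left out, which kept 15084, of which 1223 lacked exactly 1 symbol and were left out of the gene counts. Of the probe sets of a gene the one with the highest mean was used, which gave 9079 genes. The Scgb1a1 and Sftpc probe sets lay at the top of the signal scale, where quantile normalization limits what can be seen.

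Groups were strain by stage as the labels give them, 10 in all, with male and female pools of a group as its replicates. In R 4.3.3 with limma 3.58.1, 1 model with a term for each group and a term for sex was fitted to the 21 arrays (lmFit, contrasts.fit, eBayes with trend), with 10 residual degrees of freedom and 16.9 after shrinkage. Tests were two-sided, p values were adjusted by Benjamini and Hochberg over the genes of a comparison, and an adjusted p under 0.05 was a call, with no fold threshold. The C57BL/6 group at 6 weeks had 1 array, so only differences from the controls and percentiles of list medians among 10000 random lists were given. No paired analysis was possible because each array was a pool of different mice and no mouse was measured more than once as far as the labels say. Differences between strains in the response, and a dose term and a term for sex by treatment in models of their own, were tested in the same way. Precision was limited by the number of arrays, mostly 2 per group; the median SE of a change was 0.198 for 2 arrays against 2.

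The gene lists, 27 in number, were fixed: collagens and extracellular matrix, matrix proteases and inhibitors, TGF-beta pathway, smooth muscle and myofibroblast, macrophage, neutrophil, B and plasma cell, T and NK cell markers, chemokines and cytokines, complement and acute phase, antigen presentation, interferon-stimulated genes, p53 targets, cell cycle, type 2 and type 1 alveolar epithelium, airway epithelium, endothelium, heart and skeletal muscle, adipocytes, red cells, mast cells and eosinophils, antioxidant and NRF2 targets, glucocorticoid and fasting response, circadian clock, immediate early and heat shock, and bleomycin handling. Each was tested with camera at a preset correlation of 0.01, beside it with an estimated correlation and with fry, adjusted over the lists of a comparison. Some genes are in several lists. Calls of 2 strains were compared by Fisher's exact test, adjusted over the tests. Comparisons that share controls were set beside 100 simulations of unchanged groups.

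The design, the tests, the lists, the filters, the naming rule and the alternative settings that follow were chosen before the data were examined. Named were the 8 genes with the largest rise and the 8 with the largest fall among those called in a comparison (the 3 smallest p where none was), up to 4 members per list with the smallest p in the 3 week, moribund and strain-response comparisons, 10 fixed genes of which 9 were tested, and sex-linked genes. These settings were the deposited scaling, offsets of 1 and 64, no dim filter or a filter on the lower 50 percent, no sex term, only the arrays of the strains compared, every probe set, array weights, an adjusted p under 0.10, leaving out each array, A/J arrays at the doses of the other strains only, and the list tests named above. Added after the data were seen were scaling to 1 median, array brightness or the Gapdh ratio as a covariate, and fits without the C3H/HeJ female 6 week array or without the 2 male arrays with the highest Xist.

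The procedure was tested on simulated data in which 200 genes were changed, and it recovered 96.5 to 100 percent of changes of 4-fold size. Of 2-fold changes it recovered 76 to 90 percent within strains and 26.5 percent for the difference in response between C57BL/6 and C3H/HeJ. False calls numbered 5 to 17 per simulation within strains, and 2 and 6 for that difference. The simulated genes varied independently, with the same spread on every array. Probe sets with several symbols or none, probe level data and the time of the moribund mice were not used here.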

Results

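Gene expression was measured in the whole right lung of 3 inbred mouse strains, A/J, C57BL/6 and C3H/HeJ, on 21 Affymetrix arrays. Treated mice had received bleomycin, an antitumour drug that breaks DNA and injures the lung, from an osmotic minipump. Each array held the RNA of a pool of several mice, so the arrays of a group were separate pools, mostly 1 of males and 1 of females. The A/J groups were control (n = 2 pools), 3 weeks (n = 4) and 6 weeks (n = 2). The C57BL/6 groups were control (n = 2), 3 weeks (n = 2), 6 weeks (n = 1) and moribund mice, for which no time was given (n = 2). The C3H/HeJ groups were control, 3 weeks and 6 weeks (n = 2 each). Males had mostly received 100 and females 125 mg/kg, and the A/J group at 3 weeks also held a male pool at 80 and a female pool at 100 mg/kg. What the control mice received is not given in the sources used here. Array medians ran from 58.4 to 111 as deposited, a ratio of 1.90, and log2 signals of any 2 arrays correlated across genes at 0.931 to 0.980. After quantile normalization 9079 genes were tested, and 454 genes would pass an unadjusted p of 0.05 by chance in each comparison.

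On the first principal component, which held 30.4% of the variance, treated C57BL/6 arrays lay between 20.4 and 34.1. The other arrays lay between −19.5 and 7.30, the C57BL/6 controls at −2.92 and −2.30.

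**Figure D1:**
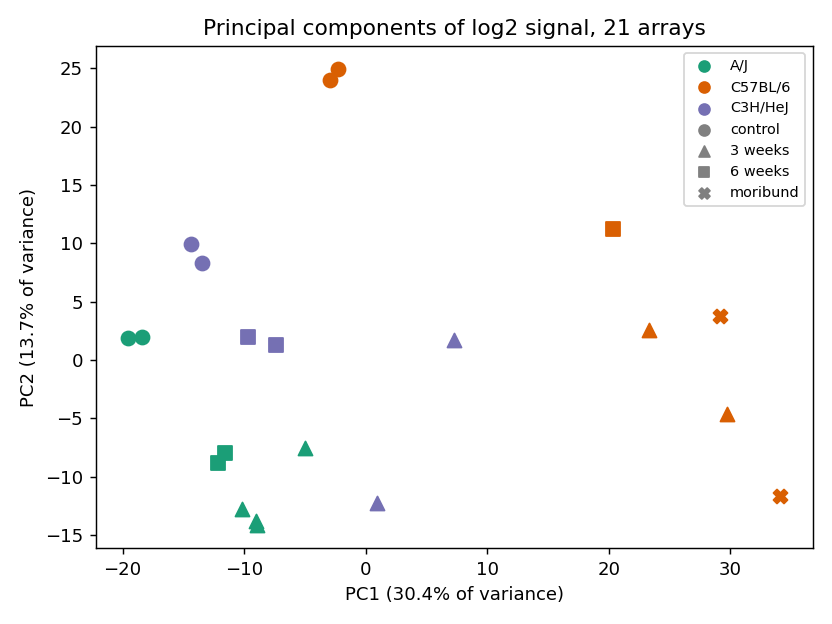
Principal component scores of the log2 signals of the 21 arrays (x axis, component 1, 30.4% of variance; y axis, component 2, 13.7% of variance), each point an array, colour for strain and shape for stage. The treated C57BL/6 arrays lie at 20.4 to 34.1 on component 1 and all other arrays at or below 7.30.

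The series title names the strain dependence of the lung's response to bleomycin. The mean of the 3 strains' changes at 3 weeks was taken first, from 8 treated and 6 control arrays. A single strain can drive this mean, so a gene named here need not have changed in each strain. Among the largest rises of single genes were those of Mmp12, a macrophage elastase, by 2.95 on the log2 scale (SE 0.26, adjusted p = 7.5e-07), Saa3, an acute phase protein, by 2.94 (SE 0.18), Trem2 by 2.69 (SE 0.16), Gpnmb by 2.37 (SE 0.10) and the metalloprotease inhibitor Timp1 by 2.13 (SE 0.14). Cdkn1a, a p53 target that arrests the cell cycle, rose by 1.95 (SE 0.11), Lcn2 by 2.07 (SE 0.07), Tnc by 1.98 (SE 0.19), Fn1 by 1.08 (SE 0.10), Col1a1 by 1.02 (SE 0.13) and Col3a1 by 0.58 (SE 0.10). The largest falls were in the muscle oxygen store Mb (−1.95, SE 0.26), an immunoglobulin segment, Ighv14-2 (−1.79, SE 0.25), Thrsp (−1.60, SE 0.18), Chad (−1.53, SE 0.33), Igfbp3 (−1.49, SE 0.21), Fabp1 (−1.29), Acaa1b (−1.26) and Adipoq (−1.25). Psrc1 rose by 2.21 (SE 0.16). Tgfb1 did not pass (0.39, SE 0.14, adjusted p = 0.068), nor did Blmh, which encodes the hydrolase that inactivates bleomycin (0.07, SE 0.10). In all, 1541 genes passed, 721 higher and 820 lower, 110 of them by more than 2-fold, and 2695 had an unadjusted p under 0.05. Over these 1541 genes the median change in the direction of the mean was 0.30 in A/J, 0.63 in C57BL/6 and 0.43 in C3H/HeJ. Each strain's own change enters the mean by which the genes were chosen.

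Of the 37 macrophage markers 27 rose and 2 fell in the mean of the strains (31 and 2 adjusted over the list alone; median 0.67). Of the 28 matrix proteases and inhibitors 18 rose (20 and 1 fall adjusted over the list alone; median 0.64), among them Serpina3n (1.84), Ctsd (1.02) and Ctsb (0.73). The 49 matrix genes gave 26 rises and 2 falls (28 and 2 adjusted over the list alone; median 0.38), with Lox at 1.43, Col5a2 at 1.26 and Tgfbi at 1.16. Neutrophil markers rose in 12 of 15 (median 0.88), with S100a8 at 1.84 and Csf3r at 1.37. Complement and acute phase genes rose in 12 of 21 (median 0.43), with C3ar1 at 1.69 and C1qc at 1.61. Interferon-stimulated genes rose in 17 of 34 (median 0.40), with Cxcl10 at 1.85, Irf7 at 1.36 and Oas3 at 1.36. Cell cycle genes rose in 30 of 55 (39 adjusted over the list alone; median 0.42), with Birc5 at 1.35, Mki67 at 1.35 and Rrm2 at 1.15. Of 36 p53 targets 12 rose and 3 fell (median 0.17), with Phlda3 at 1.19, Ccng1 at 1.09 and Aen at 0.87. Chemokines rose in 10 of 32 and fell in 1 (median 0.14), with Ccl9 at 1.77, Ccl8 at 1.53 and Ccl6 at 1.02. Each of these 9 lists passed camera with an estimated correlation too, at adjusted p from 1.8e-04 (proteases) to 0.041 (chemokines).

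Heart and skeletal muscle genes fell in 17 of 26 (20 adjusted over the list alone; median −0.65), with Sln at −1.20, Tnni3 at −1.17, Myh6 at −1.15 and Fabp3 at −1.01. Airway genes fell in 12 of 30 and rose in 3 (median −0.26), with Tppp3 at −0.96 and Fmo1 at −0.79 against Retnla at 1.68 and Clca3a1 at 0.98. Both lists passed with an estimated correlation (adjusted p = 0.0351 and 0.0267). B and plasma cell markers fell in 11 of 20 (median −0.43), with Cd79b at −1.14, Ms4a1 at −1.0, Cd79a at −0.96 and Jchain at −0.68, but the list gave adjusted p = 0.0919 with an estimated correlation. The endothelial list gave 16 falls and 4 rises of 41 genes, with Tek at −0.64, Emcn at −0.52 and Hpgd at −0.41. Eln, a matrix gene that this list also holds, rose by 1.58. The list did not pass camera with an estimated correlation (adjusted p = 0.254). In the TGF-beta list 6 of 36 genes rose and 4 fell, with Fst at 0.99, Ltbp2 at 0.83 and Fstl1 at 0.69 against Bmp6 at −0.88, and the list did not pass (adjusted p = 0.414). The antioxidant list gave 6 rises and 10 falls of 39, with Mt2 at 1.24 against Gsta3 at −0.87, Gstm1 at −0.73 and Aox1 at −0.71; its median was 0.02 while its mean was −0.05, and it did not pass (adjusted p = 0.338).

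With the scaling as deposited the median of all genes was −0.27 in this mean, and the split of the calls moved from 721 higher and 820 lower to 187 and 1864 (9.12% higher). Of the 1541 genes 1005 kept their call there. Cald1, Ier5 and Tapbp turned from small rises to −0.03, −0.01 and −0.05, and the medians of the chemokine, p53 and antigen presentation lists turned to −0.09, −0.08 and −0.20, each above the median of all genes. Without the C57BL/6 male 3 week array 1014 genes passed.

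**Figure D2:**
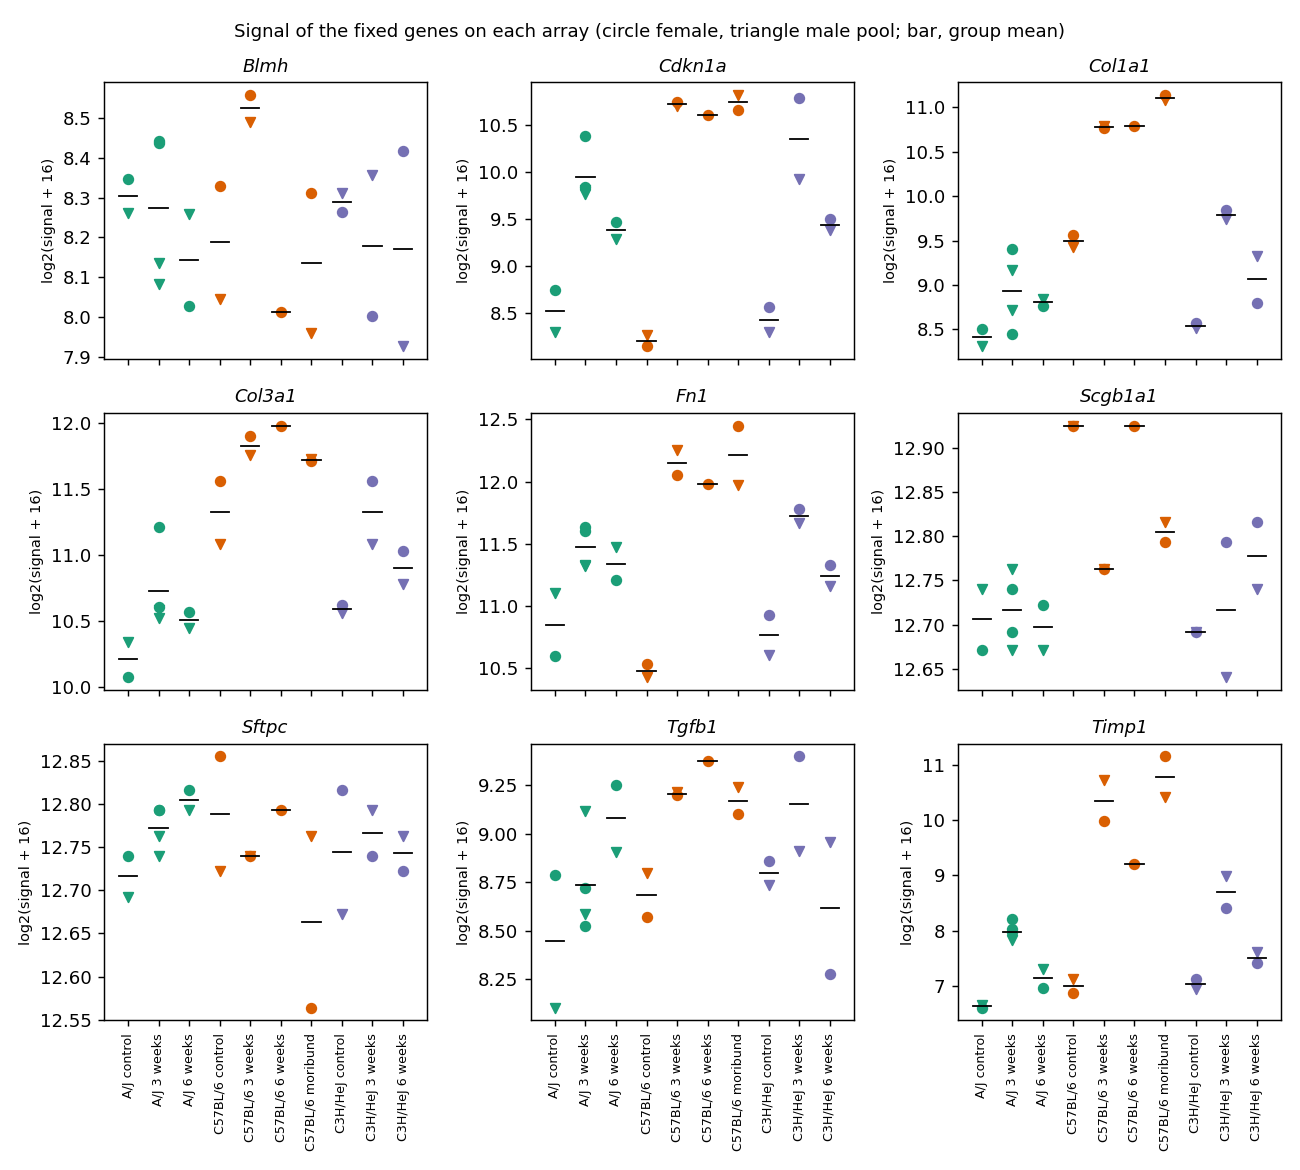
Signal of the 9 genes fixed beforehand and tested (y axes, log2 of normalised signal plus 16) in the 10 groups of arrays (x axes), each point a pool, circle for female and triangle for male, bar for the group mean. Cdkn1a rose by 1.42, 2.51 and 1.92 at 3 weeks in A/J, C57BL/6 and C3H/HeJ, while Sftpc and Scgb1a1 moved by at most 0.16 in size.

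In C57BL/6 at 3 weeks (n = 2 against 2) Saa3 rose by 3.71 (SE 0.32, adjusted p = 9e-07), Gpnmb by 3.58 (SE 0.19, adjusted p = 3e-09), Timp1 by 3.36 (SE 0.26) and Trem2 by 3.31 (SE 0.29). Next came Mmp12 by 3.27 (SE 0.48), the matrix protein Tnc by 3.26 (SE 0.35), Ms4a6d by 3.00 (SE 0.26) and the complement gene C1qb by 2.90 (SE 0.31). Cdkn1a rose by 2.51 (SE 0.20), Fn1 by 1.67 (SE 0.18) and Col1a1 by 1.28 (SE 0.23). The largest falls were in Mb (−2.69, SE 0.46), Pcolce2 (−2.19, SE 0.18), the adipocyte gene Car3 (−2.13, SE 0.30), Bex2 (−2.10, SE 0.23), Thrsp (−2.04, SE 0.32), Cyp1a1 (−1.92, SE 0.24), Irx3 (−1.89, SE 0.43) and Lrat (−1.86, SE 0.35). Col3a1 (0.51, SE 0.18, adjusted p = 0.076), Tgfb1 (0.52, SE 0.25), Blmh (0.34, SE 0.18), Sftpc (−0.05) and Scgb1a1 (−0.16) did not pass. The last pair sat at the top of the signal scale, where quantile normalization leaves little room for change. A total of 1186 genes passed, 644 higher and 542 lower, 367 by more than 2-fold, with 2385 at an unadjusted p under 0.05.

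Macrophage markers rose in 26 of 37 and fell in 1 (27 and 1 adjusted over the list alone; median 1.13), among them Cd68 at 1.66 and Ctsd at 1.43. Matrix proteases and inhibitors rose in 16 of 28 (16 adjusted over the list alone; median 0.90), with Serpina3n at 2.84 and Mmp14 at 1.82. Matrix genes rose in 25 of 49 and fell in 2 (31 and 4 adjusted over the list alone; median 0.62), with Lox at 2.11, Col5a2 at 1.88 and Tgfbi at 1.74. Complement and acute phase genes rose in 10 of 21 and fell in 1 (median 0.41), with C1qc at 2.80 and C1qa at 2.57. Chemokines rose in 10 of 32 and fell in 1 (median 0.33), with Cxcl10 at 2.90, Ccl9 at 2.64 and Ccl8 at 2.18. Cell cycle genes rose in 25 of 55 (31 adjusted over the list alone; median 0.56), with Birc5 at 1.68, Rrm2 at 1.51, Anln at 1.27 and Cks1b at 1.27. Of the p53 targets 10 rose and 2 fell (median 0.28), with Gadd45g at 1.95, Phlda3 at 1.44 and Aen at 0.96. Heart and skeletal muscle genes fell in 14 of 26 (18 adjusted over the list alone; median −0.92), with Myl7 at −1.54, Tnni3 at −1.47, Sln at −1.45 and Myl4 at −1.27. Airway genes fell in 11 of 30 and rose in 4 (median −0.38), with Tppp3 at −1.68 and Fmo1 at −1.42 against Retnla at 2.16 and Clca3a1 at 1.69. These 9 lists passed with an estimated correlation at adjusted p from 7.0e-04 (proteases) to 0.0491 (muscle).

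Further lists passed camera in C57BL/6 only with its preset correlation. Neutrophil markers rose in 9 of 15 (median 0.95; adjusted p = 0.0726 with an estimated correlation), with Lcn2 at 1.81, S100a8 at 1.70, Csf3r at 1.02 and Ncf4 at 0.93. Interferon-stimulated genes rose in 12 of 34 and fell in 1 (median 0.42; adjusted p = 0.102 with an estimated correlation), with Irf7 at 1.97, Ifit1 at 1.43 and Oas1a at 1.26. Endothelial genes fell in 18 of 41 and rose in 4 (22 and 5 adjusted over the list alone; median −0.45; adjusted p = 0.0772 with an estimated correlation), with Car4 at −1.17, Hpgd at −0.99 and Tek at −0.89 against Eln at 2.01. Type 2 alveolar genes fell in 9 of 29 and rose in 1 (median −0.39; adjusted p = 0.096 with an estimated correlation), with Etv5 at −1.38, Fgfr2 at −1.08 and the surfactant gene Sftpa1 at −0.60 against Ctsh at 0.97. Type 1 alveolar genes fell in 5 of 17 and rose in 2 (median −0.39; adjusted p = 0.152 with an estimated correlation), with Vegfa at −0.73, Limch1 at −0.68, Cav1 at −0.64 and Hopx at −0.47. B and plasma cell markers fell in 6 of 20 (median −0.61; adjusted p = 0.378 with an estimated correlation), with Ighm at −1.75, Ms4a1 at −1.55, Cd79a at −1.36 and Cd79b at −1.32. Red cell genes fell in 4 of 11 (median −0.50; adjusted p = 0.0726 with an estimated correlation), with Hbb-b2 at −1.50, Alas2 at −1.23, Slc4a1 at −1.14 and Tfrc at −0.59. Adipocyte genes fell in 5 of 13 and rose in 1 (median −0.52; adjusted p = 0.208 with an estimated correlation), with Adipoq at −1.78 and Acly at −0.52 against Lpl at 0.65. Antigen presentation genes rose in 3 of 24 (Ctss 1.67, Ifi30 1.29, Cd86 0.70; adjusted p = 0.393 with an estimated correlation) and glucocorticoid and fasting genes in 7 of 27 (Mt2 2.41, Fkbp5 1.25; adjusted p = 0.393 with an estimated correlation).

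The remaining lists did not pass camera in C57BL/6 at 3 weeks. In the TGF-beta list 4 of 36 genes rose and 5 fell (adjusted p = 0.57), with Fst at 2.34, Ltbp2 at 1.88 and Fstl1 at 1.27 against Bmp6 at −1.35. The smooth muscle and myofibroblast list gave 2 rises and 1 fall of 18 (camera adjusted p = 0.506), with S100a4 at 1.95 and Cald1 at 0.77 against Itga8 at −1.16. Cnn1 (−0.65) did not pass. The antioxidant list gave 4 rises and 9 falls of 39 (adjusted p = 0.24), with Gsta3 at −1.45, Aox1 at −1.28 and Gstm1 at −1.25. Of 24 T and NK cell markers only Icos rose (0.89; 0 adjusted over the list alone, where limma was used, and adjusted p = 0.959 for the list). Of 6 mast cell and eosinophil markers only Kit fell (−0.63; list adjusted p = 0.512). Of 15 bleomycin handling genes only Abcb1a fell (−0.73; list adjusted p = 0.668, median −0.03 and mean 0.00). Immediate early genes gave 1 rise, Egr2 at 1.09, and 4 falls of 33, with Nr4a1 at −1.08 (−0.27 without the male control), Jun at −0.81 and Klf2 at −0.74 (list 0.512). None of 14 clock genes passed with limma over all genes or over the list alone (list 0.0993, median −0.44).

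With the deposited scaling 387 genes passed in C57BL/6 at 3 weeks, 162 higher and 225 lower (41.9% higher against 54.3%), at an all-gene median of −0.16, and 369 of the 1186 genes kept their call; 18 of the 99 named genes that passed lost theirs. Scaling every array to 1 median gave 672 higher and 335 lower (66.7% higher). Leaving out the male 3 week array left 427 genes, the male control 553 and the female control 627.

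**Figure D3:**
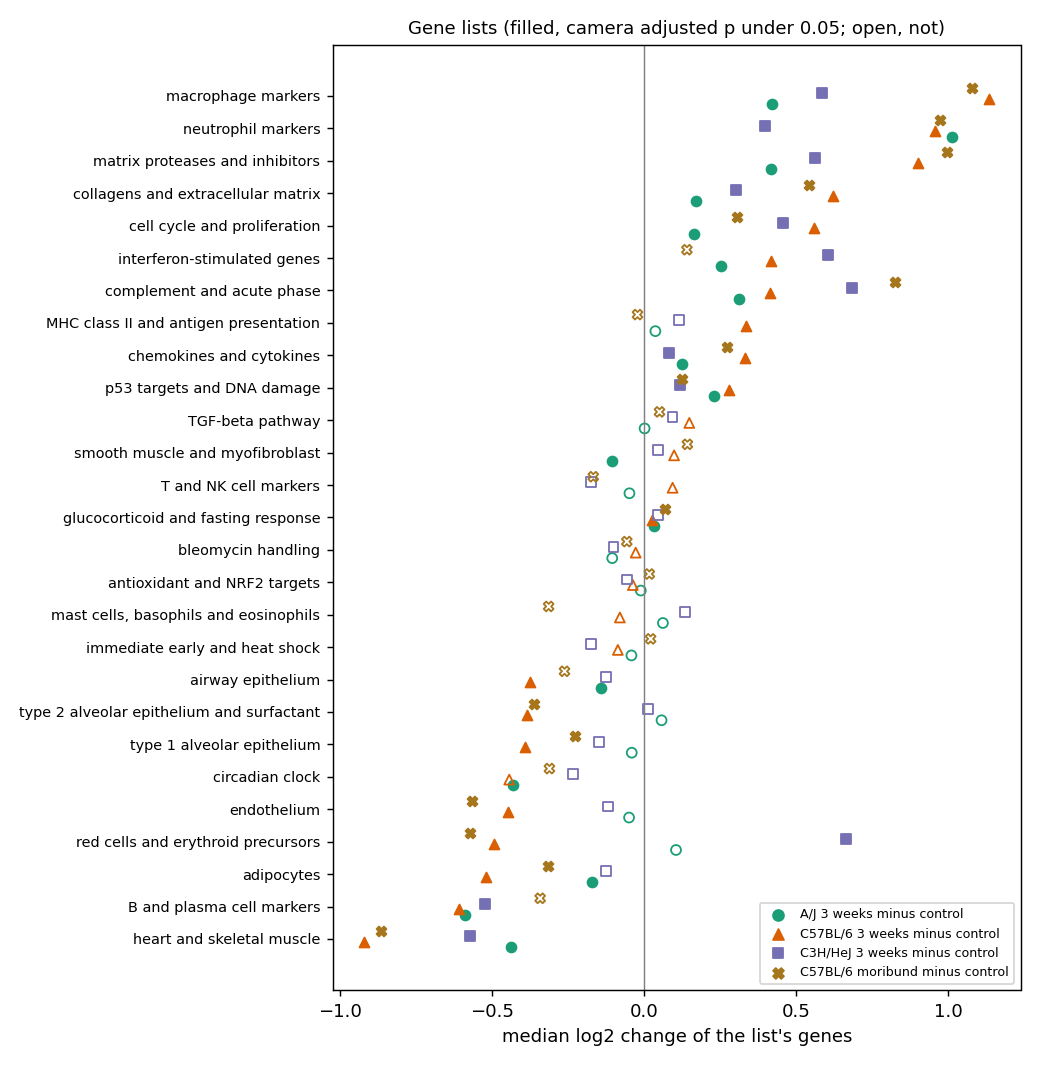
Median log2 change of the genes of each of the 27 lists (x axis) in 4 comparisons with control, each point a list (y axis), filled where camera with its preset correlation passed and open where it did not. Macrophage markers lie at 0.42, 1.13, 0.58 and 1.08 in A/J, C57BL/6, C3H/HeJ and moribund C57BL/6, and heart and skeletal muscle genes at −0.44, −0.92, −0.57 and −0.87.

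In C3H/HeJ at 3 weeks (n = 2 against 2) Mmp12 rose by 3.22 (SE 0.48, adjusted p = 0.0012), Psrc1 by 2.73 (SE 0.29), Trem2 by 2.66 (SE 0.29) and Saa3 by 2.61 (SE 0.32). They were followed by the antiviral gene Oas3 by 2.45 (SE 0.20), Cxcl10 by 2.28 (SE 0.32), Lcn2 by 2.23 (SE 0.13) and Tnc by 2.04 (SE 0.35). Cdkn1a rose by 1.92 (SE 0.20), Timp1 by 1.67 (SE 0.26), Col1a1 by 1.25 (SE 0.23), Fn1 by 0.96 (SE 0.18) and Col3a1 by 0.73 (SE 0.18). The largest falls were in Ighv14-2 (−2.07, SE 0.45), Zdhhc1 (−2.03, SE 0.36), Mb (−2.02, SE 0.46), Nup107 (−1.88), Abca2 (−1.86), Thrsp (−1.74), Fabp1 (−1.57) and Atp6v1c2 (−1.54). Tgfb1 (0.35), Blmh (−0.11), Sftpc (0.02) and Scgb1a1 (0.03) did not pass. The count was 257 genes, 158 higher and 99 lower, 109 by more than 2-fold, with 1491 at an unadjusted p under 0.05.

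Macrophage markers rose in 15 of 37 and fell in 1 (20 and 1 adjusted over the list alone; median 0.58), with Gpnmb at 1.64, Marco at 1.61 and Ctsk at 1.60. Matrix proteases and inhibitors rose in 11 of 28 (15 adjusted over the list alone; median 0.56), and matrix genes in 11 of 49 (15 adjusted over the list alone; median 0.30), with Tgfbi at 1.13, Col5a2 at 1.12, Col1a2 at 0.94 and Col4a1 at 0.74. Complement and acute phase genes rose in 10 of 21 (median 0.68), with C3ar1 at 1.64 and C1qa at 1.46. Interferon-stimulated genes rose in 9 of 34 (17 adjusted over the list alone; median 0.60), with Irf7 at 1.55 and Ifit1 at 1.40. Cell cycle genes rose in 15 of 55 (21 adjusted over the list alone; median 0.46), with Birc5 at 1.76, Tk1 at 1.47, Rrm2 at 1.26 and Top2a at 1.14. Of the p53 targets 7 of 36 rose (median 0.12), with Ccng1 at 1.36, Phlda3 at 1.19 and Aen at 0.93. These 7 lists passed with an estimated correlation at adjusted p from 2.0e-04 to 0.0335.

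Neutrophil markers rose in 6 of 15 in C3H/HeJ (median 0.40; adjusted p = 0.054 with an estimated correlation), with S100a8 at 1.28, Csf3r at 1.2 and Ncf4 at 0.63. Chemokines rose in 6 of 32 (adjusted p = 0.0953 with an estimated correlation), with Ccl9 at 1.67, Ccl8 at 1.65 and Il1b at 1.18. Heart and skeletal muscle genes fell in 7 of 26 (12 adjusted over the list alone; median −0.57; adjusted p = 0.127 with an estimated correlation), with Myh6 at −1.20, Fabp3 at −1.09, Tnni3 at −1.04 and Sln at −0.93. Red cell genes had a median of 0.66 with 0 past limma's threshold over all genes and 2 higher adjusted over the list alone (adjusted p = 0.054 with an estimated correlation), and B and plasma cell markers a median of −0.52 with Cd79b at −1.27 (adjusted p = 0.175 with an estimated correlation). Single genes that passed in lists that did not were Cd3d (−1.52), Lat (−1.17), Bpifa1 (−1.07), Bmp6 (−0.94), Klf15 (−0.91), Tek (−0.87), Rtkn2 (−0.80), Fmo1 (−0.68), Tppp3 (−0.63), Gstm1 (−0.63), Tap1 (0.98), S100a4 (1.15), Eln (1.55) and Retnla (1.91). Pdgfra fell by −0.72 with the probe set used and rose by 0.16 with its second. Smooth muscle genes had a median of 0.04 and a mean of −0.02, and did not pass.

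On the values as deposited 21 genes were higher and 65 lower in C3H/HeJ (24.4% higher against 61.5%), at an all-gene median of −0.32, and 71 of the 257 kept their call; the medians of the matrix, chemokine and p53 lists turned to −0.05, −0.20 and −0.10. Scaling to 1 median gave 114 higher and 173 lower. Without the male control 68 genes passed, without the female control 80 and without the female 3 week array 145.

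In A/J at 3 weeks (n = 4 against 2) the neutrophil gene S100a9 rose by 2.78 (SE 0.30, adjusted p = 9.3e-05), S100a8 by 2.55 (SE 0.24), Saa3 by 2.5 (SE 0.27) and Mmp12 by 2.37 (SE 0.41). Lcn2 rose by 2.17 (SE 0.12), Trem2 by 2.11 (SE 0.25), Ngp by 2.02 (SE 0.28), Gpnmb by 1.90 (SE 0.16), Cdkn1a by 1.42 (SE 0.18) and Timp1 by 1.35 (SE 0.22). The largest falls were in heart genes, Nppa (−1.66, SE 0.36), Myh6 (−1.24, SE 0.18) and Sln (−1.23, SE 0.16), and in Fabp1 (−1.52, SE 0.27), Zbtb14 (−1.08), Abi3bp (−1.02), Cnn1 (−1.02) and Fabp3 (−1.01). Col1a1 (0.53, SE 0.20, adjusted p = 0.32), Col3a1 (0.52, SE 0.16), Fn1 (0.62, SE 0.15, adjusted p = 0.068), Tgfb1 (0.29), Blmh (−0.03), Sftpc (0.06) and Scgb1a1 (0.01) did not pass. The count was 94 genes, 72 higher and 22 lower, 45 by more than 2-fold, with 996 at an unadjusted p under 0.05.

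Neutrophil markers rose in 8 of 15 (11 adjusted over the list alone; median 1.01), with Csf3r at 1.89. Macrophage markers rose in 8 of 37 (17 and 1 fall adjusted over the list alone; median 0.42), with Ctsd at 0.84 and Lgals3 at 0.83. Matrix proteases and inhibitors rose in 7 of 28 (16 adjusted over the list alone; median 0.42), with Serpina3n at 1.52, and complement and acute phase genes in 4 of 21 (10 adjusted over the list alone; median 0.31), with C3ar1 at 1.16. The p53 targets rose in 4 of 36 (median 0.23), with Phlda3 at 0.95, Ccng1 at 0.87 and Aen at 0.72. Heart and skeletal muscle genes fell in 5 of 26 (12 adjusted over the list alone; median −0.44), with Tnni3 at −0.99. No B or plasma cell marker passed limma over all genes while 10 of 20 fell adjusted over the list alone (median −0.59), and airway genes gave 1 rise, Retnla at 0.97, and 2 falls, Muc5b at −0.76 and Tppp3 at −0.56 (median −0.14). These 8 lists passed with an estimated correlation at adjusted p from 4.4e-04 to 0.0418.

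Matrix genes rose in 6 of 49 in A/J (14 and 4 falls adjusted over the list alone; median 0.17; adjusted p = 0.128 with an estimated correlation), with Lox at 1.43, Col5a2 at 0.79, Col4a2 at 0.44 and Sparc at 0.41. Chemokines rose in 5 of 32 (Ccl9 1.01, Il1rn 1.01, Ccl6 0.93, Il1b 0.90), cell cycle genes in 2 of 55 (Mki67 1.06, Cks1b 0.63) and interferon-stimulated genes in 1 of 34 (Ifi202b 1.18), each list at adjusted p = 0.145 with an estimated correlation. The smooth muscle and myofibroblast list gave S100a4 at 1.04 against Cnn1 and Myh11 (−0.89), and the adipocyte list Plin4 at −0.81. The endothelial list gave Lyve1 at 0.94 and Eln, a matrix gene it also holds, at 1.16 against Emcn (−0.66).

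With the deposited scaling 16 genes were higher and 49 lower in A/J (24.6% higher against 76.6%), at an all-gene median of −0.35, and 35 of the 94 kept their call. There the medians of the matrix, chemokine, interferon, p53, cell cycle and glucocorticoid lists turned to −0.19, −0.22, −0.11, −0.15, −0.13 and −0.33. Without the male control 27 genes passed and without the female control 34. The higher minus the lower dose within A/J at 3 weeks gave 0 genes with limma and 355 at an unadjusted p under 0.05. The smallest p values were those of Appbp2os (−1.79, SE 0.28, adjusted p = 0.092), Cort (−1.66, SE 0.30) and Apc2 (1.42, SE 0.27), none of which passed. Over the 94 genes the median change in the called direction was 0.88 in the male pool at 80, 0.99 in the male pool at 100, 0.91 in the female pool at 100 and 1.06 in the female pool at 125 mg/kg.

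Calls were shared between strains, which have separate controls. The strains were fitted in 1 model, though, with the same variance estimate for a gene in each, and Fisher's exact test treats genes as independent. The counts by chance and the p values below allow for neither. A/J and C57BL/6 shared 61 higher genes (5.11 by chance) and 11 lower (1.31), A/J and C3H/HeJ 56 (1.25) and 9 (0.24), and C57BL/6 and C3H/HeJ 115 (11.2) and 52 (5.91), with Fisher's exact adjusted p at most 1.2e-08. C57BL/6 and C3H/HeJ shared 18 higher genes with the deposited scaling, 67 without the C3H/HeJ male 3 week array, 45 without the C3H/HeJ male control and 48 without the C3H/HeJ female control. In all 3 strains 51 genes were higher, among them Mmp12, Gpnmb, Trem2, Saa3, Lcn2, Timp1, Cdkn1a, Phlda3, Mki67 and the matrix genes Eln and Col5a2. The 8 genes lower in all 3 were Abi3bp, Fabp3, Igfbp5, Myh6, Prickle1, Sln, Tnni3 and Tppp3; these lists go beyond the naming rule and were chosen after their values were seen.

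Whether strains differed in their response was tested as a difference of differences. Against A/J, the change in C57BL/6 was more positive in Tnc (2.63, SE 0.47, adjusted p = 0.0099), Cxcl10 (2.53, SE 0.42), C1qb (2.21, SE 0.40), Fst (2.19, SE 0.44), Armcx4 (2.18, SE 0.21), the scavenger receptor Msr1 (2.14, SE 0.42), C1qc (2.08, SE 0.28) and Timp1 (2.01, SE 0.34). It was more negative, which includes larger falls, smaller rises and opposite directions, in Ngp (−2.06, SE 0.43), Gjb6 (−1.93, SE 0.42), Bex2 (−1.85, SE 0.30), Cyp1a1 (−1.85, SE 0.32), Pcolce2 (−1.75, SE 0.23), Dpep1 (−1.73, SE 0.29), Hbb-b2 (−1.73, SE 0.35) and Slc7a10 (−1.72, SE 0.24). The count was 142 genes, 84 higher and 58 lower, 107 by more than 2-fold, with 1361 at an unadjusted p under 0.05. Macrophage markers gave 9 higher of 37 (19 adjusted over the list alone; median 0.59), with Fcgr1 at 1.67, Gpnmb at 1.69 and Cd68 at 1.18. Proteases gave 3 of 28 (median 0.37), with Ctss at 1.25 and Mmp14 at 1.23, and complement gave 5 of 21 (median 0.23), with C1qa at 1.88 and Cfb at 1.46. Red cell genes had a median of −0.62 with 1 lower (7 adjusted over the list alone). These 4 lists passed with an estimated correlation at adjusted p = 0.0408.

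Matrix genes were higher in 8 of 49 in that difference (10 and 2 lower adjusted over the list alone; median 0.43; adjusted p = 0.0584 with an estimated correlation), with Fmod at 1.31, Tgfbi at 1.13 and Col5a2 at 1.09. Type 2 alveolar genes were lower in 2 of 29 (Etv5 −1.39, Sftpa1 −0.72) and endothelial genes in 3 of 41 (Car4 −1.12, Eng −1.08 with its second probe set at −0.09, Ptprb −1.01), both lists at adjusted p = 0.0992 with an estimated correlation. For type 1 genes the median of −0.21 turned to 0.00 with the deposited scaling. Neutrophil markers had a median of 0.02 while their mean was −0.38 and camera's direction was lower (adjusted p = 0.44 with an estimated correlation). With the deposited scaling 22 genes were higher and 3 lower (88.0% higher against 59.2%), at an all-gene median of 0.19, and 23 of the 142 kept their call; 32 of the 50 named genes lost theirs, and 41 did in some fit that left out an array. Without the A/J male control 17 genes passed, without the A/J female control 45, without the A/J male array at 100 mg/kg 93, without the C57BL/6 male 3 week array 18, without the C57BL/6 male control 64 and without the C57BL/6 female control 51.

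Against C3H/HeJ, the change in C57BL/6 was more positive in Pstpip2 (2.15, SE 0.41, adjusted p = 0.037), Gpnmb (1.94, SE 0.26), Armcx4 (1.94, SE 0.22), Ajuba (1.80, SE 0.32), Hmox1 (1.78, SE 0.35), Pdzrn3 (1.73, SE 0.26), Apoe (1.72, SE 0.29) and Myc (1.70, SE 0.35). It was more negative in Hbb-b2 (−2.32, SE 0.37), Pcolce2 (−1.81, SE 0.25), Oas3 (−1.50, SE 0.29), Dcn (−1.48, SE 0.30), Pttg1 (−1.48, SE 0.20), Slc7a10 (−1.40), Polr2a (−1.26) and Klf5 (−1.25). Of these Pcolce2 fell further in C57BL/6 (−2.19 against −0.37) and Oas3 rose less (0.96 against 2.45). Pttg1 was already 2.53 higher in C57BL/6 than in C3H/HeJ control lungs, so its changes started from unlike levels. Hbb-b2 had the opposite sign (−1.50 against 0.82), but its change in C3H/HeJ did not pass. The count was 27 genes, 14 higher and 13 lower, 25 by more than 2-fold, with 1336 at an unadjusted p under 0.05. Red cell genes had a median of −0.65 (6 of 11 lower adjusted over the list alone), the only list to pass with an estimated correlation (adjusted p = 0.0334). Macrophage markers had a median of 0.57 (18 and 2 lower adjusted over the list alone), with adjusted p = 0.208 with an estimated correlation, as for type 2 alveolar genes (median −0.36). Endothelial genes had a median of −0.22, which turned to 0.00 with arrays scaled to 1 median (adjusted p = 0.258 with an estimated correlation). Interferon-stimulated genes (median 0.02, mean −0.06) did not pass (adjusted p = 0.538), and in the TGF-beta and antioxidant lists, which did not pass, the median was 0.06 and camera's direction lower. Only 2 genes passed with the deposited scaling, both higher, at an all-gene median of 0.16, and scaling to 1 median gave 54 higher and 5 lower (91.5% higher). Without the C57BL/6 male 3 week array 5 genes passed, without the C57BL/6 male control 15, without the C57BL/6 female control 16, without the C3H/HeJ male control 7, without the C3H/HeJ female control 9 and without the C3H/HeJ male 3 week array 184.

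A/J and C3H/HeJ differed in the response of 1 gene, Oas3 (−1.79, SE 0.27, adjusted p = 0.0349), with 361 at an unadjusted p under 0.05; Oas3 changed by 0.67 in A/J (adjusted p = 0.092), by 0.96 in C57BL/6 and by 2.45 in C3H/HeJ. Cell cycle (median −0.27) and interferon-stimulated genes (median −0.24) were lower and neutrophil markers (median 0.36) higher in this difference by camera, but with an estimated correlation the adjusted p was 0.224, 0.234 and 0.249. Every fit that left out 1 of the arrays compared gave 0, 2 or 3 genes in place of 1.

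In moribund C57BL/6 mice (n = 2 against 2 controls) Saa3 rose by 4.10 (SE 0.32, adjusted p = 3.3e-07), Timp1 by 3.79 (SE 0.26), Gpnmb by 3.65 (SE 0.19) and Trem2 by 3.58 (SE 0.29). Tnc rose by 3.44 (SE 0.35), the metallothionein Mt2 by 3.29 (SE 0.30), Serpina3n by 3.27 (SE 0.27) and the monocyte chemokine Ccl2 by 3.16 (SE 0.43). Cdkn1a rose by 2.53 (SE 0.20), Fn1 by 1.73 (SE 0.18) and Col1a1 by 1.61 (SE 0.23). The largest falls were in Mb (−3.15, SE 0.46), Bex2 (−2.42, SE 0.23), Ppbp (−2.38, SE 0.33), Pcolce2 (−2.23, SE 0.18), Zdhhc1 (−2.08, SE 0.36), Gzma (−2.07, SE 0.36), Lrat (−2.05, SE 0.35) and Aplnr (−2.03, SE 0.29). Col3a1 (0.40), Tgfb1 (0.49), Blmh (−0.05), Sftpc (−0.12) and Scgb1a1 (−0.12) did not pass. A total of 1384 genes passed, 630 higher and 754 lower, 437 by more than 2-fold, with 2600 at an unadjusted p under 0.05.

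Macrophage markers rose in 27 of 37 in moribund mice (29 adjusted over the list alone; median 1.08) and proteases and inhibitors in 18 of 28 (21 adjusted over the list alone; median 1.0). Matrix genes rose in 24 of 49 with 2 falls (30 and 4 adjusted over the list alone; median 0.54), with Lox at 2.39 and Col5a2 at 1.95. Complement genes rose in 10 of 21 with 1 fall (median 0.83), with C1qc at 2.78 and C3ar1 at 2.51. These 4 lists passed with an estimated correlation at adjusted p from 3.2e-04 to 0.0205. Muscle genes fell in 15 of 26 (median −0.87), with Myl7 at −1.92 and Myh6 at −1.57, and neutrophil markers rose in 10 of 15 (median 0.97), with Cd177 at 1.63, Ltf at 1.52 and Mmp8 at 1.38, both lists at adjusted p = 0.0895 with an estimated correlation. Endothelial genes fell in 21 of 41 and rose in 2 (median −0.57; adjusted p = 0.123 with an estimated correlation), with Car4 at −1.41, Hpgd at −1.20 and Icam2 at −1.05. Type 2 alveolar genes fell in 11 of 29 (median −0.36; adjusted p = 0.132 with an estimated correlation), with Fgfr2 at −0.96 and Cd36 at −0.83. Red cell genes fell in 6 of 11 (median −0.57; adjusted p = 0.119 with an estimated correlation), with Slc4a1 at −1.34 and Bpgm at −1.16. Glucocorticoid and fasting genes rose in 9 of 27 and fell in 2 (adjusted p = 0.271 with an estimated correlation), with Mt1 at 2.73. The antigen presentation list had a median of −0.02 and a mean of 0.15, the antioxidant list a median of 0.02 with camera's direction lower, and neither passed. Dgat2 (−0.84) and Tfrc (−0.93) fell while their second probe sets gave 0.10 and 0.15.

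With the deposited scaling 139 genes were higher and 562 lower in moribund mice (19.8% higher against 45.5%), at an all-gene median of −0.28, and 643 of the 1384 kept their call; the p53 and glucocorticoid medians turned to −0.16 and −0.20. Without the male control 771 genes passed, without the female control 669 and without the female moribund array 713. The changes at 3 weeks and in moribund mice correlated across genes at 0.84 where simulated unchanged groups that share the same controls gave 0.50. The comparisons shared 441 higher genes (44.7 by chance) and 387 lower (45.0), with 0 in opposite directions in the limma calls; the shared controls add to these counts.

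Moribund mice against 3 weeks gave 0 genes with limma and 886 at an unadjusted p under 0.05. The smallest p values were those of Myo1f (−1.70, SE 0.28), Zmat5 (−1.49, SE 0.25) and Numbl (1.17, SE 0.20), each at adjusted p = 0.0544. By camera the interferon-stimulated genes (median −0.48; 16 of 34 lower adjusted over the list alone, with Irf7 at −0.84, Ifi47 at −0.79 and Igtp at −0.71) and the cell cycle genes (median −0.34; 4 of 55 lower adjusted over the list alone, with Mcm2 at −1.72 and Mki67 at −1.23) were lower in moribund mice, both at adjusted p = 0.379 with an estimated correlation. Without the male moribund array 52 genes passed, without the female moribund array 6, and without the male or the female 3 week array 1.

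At 6 weeks few genes passed in A/J and C3H/HeJ. The change from 3 to 6 weeks itself was not tested, so the lower counts do not show a decline. In A/J the 3 week group also had 4 arrays and the 6 week group 2. The C3H/HeJ female 6 week array had the highest Gapdh ratio of all arrays (2.08). In A/J (n = 2 against 2) S100a9 rose by 2.43 (SE 0.35, adjusted p = 0.0042), S100a8 by 2.34 (SE 0.28), Trem2 by 1.76 (SE 0.29) and Gpnmb by 1.75 (SE 0.19). So did Csf3r by 1.47 (SE 0.21), Steap4 by 1.26 (SE 0.20; 0.04 in its second probe set), Lcn2 by 1.18 (SE 0.13) and Alox5ap by 0.80 (SE 0.13), while the macrophage receptor Marco fell by 1.65 (SE 0.24). In C3H/HeJ (n = 2 against 2) Mmp12 rose by 3.70 (SE 0.48, adjusted p = 0.0016), Trem2 by 1.98 (SE 0.29) and Npy by 1.87 (SE 0.25). Smaller rises were those of Otud7a by 1.73 (SE 0.24), Psrc1 by 1.70 (SE 0.29), Oas3 by 1.60 (SE 0.20), Gpnmb by 1.46 (SE 0.19) and Ctsk by 1.30 (SE 0.22). Each strain had 10 genes past the threshold, 9 higher and 1 lower in A/J and 10 higher in C3H/HeJ, with 477 and 419 at an unadjusted p under 0.05. None of the fixed genes passed at 6 weeks with limma: Cdkn1a was at 0.86 in A/J (SE 0.20, adjusted p = 0.23) and 1.01 in C3H/HeJ (SE 0.20, adjusted p = 0.099). In the same order Timp1 was at 0.51 and 0.47, Col1a1 at 0.40 and 0.52, Col3a1 at 0.30 and 0.31, Fn1 at 0.49 and 0.48, Tgfb1 at 0.63 and −0.18, Blmh at −0.16 and −0.12, Scgb1a1 at −0.01 and 0.09, and Sftpc at 0.09 and 0.00.

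In A/J at 6 weeks neutrophil markers (median 0.78, 4 of 15 higher), proteases (0.24), complement (0.26) and p53 targets (0.12) passed camera with an estimated correlation, at adjusted p from 0.00569 to 0.0212. In C3H/HeJ proteases (0.24, 2 of 28 higher), macrophage markers (0.34, 3 of 37 higher), complement (0.30) and p53 targets (0.17) did, at adjusted p from 0.00622 to 0.0208. The genes called at 3 weeks in A/J lay on the same side at 6 weeks in 72 of 72 higher and 22 of 22 lower cases, with medians that went from 1.01 to 0.64 and from −0.85 to −0.60. In C3H/HeJ 157 of 158 and 89 of 99 did, with medians from 0.98 to 0.40 and from −0.87 to −0.21. Both stages share controls, which places genes on 1 side: simulated unchanged groups gave a correlation across genes of 0.58 in A/J against 0.68 observed, and 0.50 in C3H/HeJ against 0.50 observed. The covariance was above that of the simulations in both, 0.0456 against 0.0252 in A/J and 0.0431 against 0.0252 in C3H/HeJ. The simulated values carried no spread, so whether this excess goes beyond the effect of shared controls was not decided. The fall in the medians also follows in part from choosing genes at 3 weeks. In A/J 6 genes passed with the deposited scaling, at an all-gene median of −0.20. Without the A/J male control 3 passed, without the male 6 week array 5 and without the female control 6, and in C3H/HeJ 6 passed without the female 6 week array.

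The single C57BL/6 female pool at 6 weeks had no replicate and was not tested; a test would have had to assume that it varied like the other groups. Against the female control Gpnmb stood at 3.49, Mmp12 at 3.49, Trem2 at 3.03, Cdkn1a at 2.45, Timp1 at 2.35, Saa3 at 2.33, Col5a2 at 1.47, Fn1 at 1.45, Col1a1 at 1.22, Tgfb1 at 0.81 and Col3a1 at 0.42. Car3 stood at −1.49, Mb at −1.46, Myh6 at −1.0, Blmh at −0.32, Sftpc at −0.06 and Scgb1a1 at 0. Of the 644 genes higher at 3 weeks 618 (96.0%) were higher in this pool, and of the 542 lower genes 511 (94.3%) were lower. Both stages share the female control, which by itself places genes on 1 side, and no value for an unchanged pool was computed, so these shares show neither persistence nor decline. The medians of the macrophage list (1.10), the proteases (0.89) and the matrix list (0.43) lay above all 10000 random lists of the same size and mean level, and those of the muscle (−0.88) and adipocyte lists (−0.70) below all. Random lists give the spread of unrelated genes and not of pools or of genes that vary together, so these positions describe 1 pair of arrays only.

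**Figure D4:**
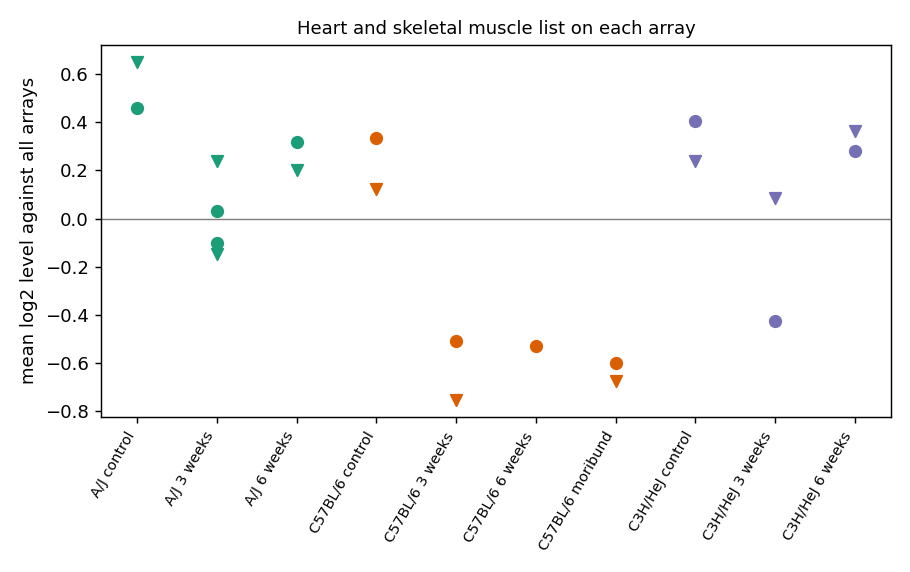
Mean log2 level of the heart and skeletal muscle list on each array relative to the mean of all arrays (y axis) in the 10 groups (x axis), each point a pool, circle for female and triangle for male. In all 3 strains every 3 week array lies below both controls of its strain, with medians of the list's changes of −0.44 in A/J, −0.92 in C57BL/6 and −0.57 in C3H/HeJ.

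For some named changes after bleomycin the second probe set of the gene gave the opposite sign or less than 50 percent of the size. Some of these smaller changes still passed in the same direction, among them C1qb in C57BL/6 and Psrc1 and Fn1 in the mean of the strains. In the mean of the strains these second probe sets gave 0.52 for Fn1, 0.96 for Psrc1, −0.27 for Gsta3, −0.16 for Jun, −0.05 for Vegfa and 0.05 for Per3. In A/J at 3 weeks they gave 0.10 for Il1rn, 0.11 for Sparc, 0.29 for Cks1b and −0.31 for Zbtb14. In C57BL/6 they gave 1.43 for C1qb, 0.76 for Fn1, −0.57 for Gsta3, −0.34 for Hpgd, −0.23 for Jun, −0.19 for Acly and −0.15 for Tfrc. In C3H/HeJ they gave 0.54 for Col5a2, −0.86 for Thrsp and 0.16 for Pdgfra at 3 weeks and 0.74 for Psrc1 at 6 weeks. In moribund mice, beside Dgat2 and Tfrc above, they gave −0.59 for Hpgd, −0.28 for Jun and −0.18 for Nr1d2. For the response of C57BL/6 against A/J, beside Eng above, they gave 0.66 for Mcm2 and −0.24 for Limch1.

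Control lungs differed between strains (n = 2 against 2 in each comparison). C57BL/6 was higher than C3H/HeJ in Rpgrip1 (3.85, SE 0.18, adjusted p = 4.7e-10), H2-D1 (3.41, SE 0.16), Trim34a (3.05, SE 0.35), Pttg1 (2.53, SE 0.14), H2-K1 (2.26), Pdxdc1 (2.25), Agtrap (2.21) and Ppbp (2.12). It was lower in Gbp2b (−4.06, SE 0.24), Cap1 (−3.34, SE 0.20), Igha (−2.73, SE 0.26), Baiap2l1 (−2.37), Rassf1 (−2.33), Tmem87a (−2.26), Alad (−2.07) and Krt79 (−1.94). It was higher than A/J in Mndal (4.05, SE 0.31), Trim34a (3.84, SE 0.35), Rpgrip1 (3.54, SE 0.18), Stk25 (2.69), Hnrnpl (2.55), Pttg1 (2.5), Bst1 (2.24) and Deptor (2.21). It was lower in Gbp2b (−4.32, SE 0.24), Igha (−3.38, SE 0.26), Cap1 (−3.33, SE 0.20), Baiap2l1 (−2.41), Tmem87a (−2.36), Jchain (−2.03), Myh7 (−2.03) and Alad (−1.98). A/J was higher than C3H/HeJ in H2-D1 (3.49, SE 0.16), Pdxdc1 (2.51, SE 0.15), Nppa (2.12), Xdh (2.12), Arap3 (1.87, with its second probe set at −0.11), H2-M3 (1.70), Bpifb1 (1.66) and Adamdec1 (1.63). Nppa is a heart gene, and uneven carry-over of heart tissue was not ruled out for its difference. It was lower in Mndal (−3.33, SE 0.31), Stk25 (−3.02, SE 0.22), Bst1 (−2.78), Rps4l (−2.03), Hbegf (−1.87), Nme7 (−1.60), Deptor (−1.55) and Procr (−1.51). The second probe set of a called gene followed, with the same sign and at least 50 percent of the size, in 103 of 231 cases over the 3 comparisons against 289 of 426 at 3 weeks in C57BL/6, so part of these differences was not shared by probe sets of 1 gene. Among the named genes the second probe set fell short of 50 percent in Agtrap (0.31), H2-K1 (0.33) and Pdxdc1 (0.85) between C57BL/6 and C3H/HeJ, in Deptor (0.78) between C57BL/6 and A/J, and in Deptor (−0.43) and Pdxdc1 (0.99) between A/J and C3H/HeJ.

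The counts were 230 genes for C57BL/6 against C3H/HeJ (104 higher, 126 lower), 254 for C57BL/6 against A/J (131 higher, 123 lower) and 87 for A/J against C3H/HeJ (40 higher, 47 lower), with 1333, 1464 and 645 at an unadjusted p under 0.05. Airway genes were higher in C57BL/6 than in C3H/HeJ (median 0.31; 4 of 30 higher, 11 and 2 lower adjusted over the list alone; adjusted p = 0.00775 with an estimated correlation) and in A/J than in C3H/HeJ (median 0.20; adjusted p = 0.0396 with an estimated correlation). Matrix genes were higher in C57BL/6 than in A/J in 8 of 49 and lower in 1 (median 0.20; adjusted p = 0.21 with an estimated correlation). Higher and lower genes with the deposited scaling were 66 and 29 (69.5% higher against 45.2%), 111 and 21 (84.1% against 51.6%) and 13 and 19, at all-gene medians of 0.14, 0.19 and −0.05; scaling to 1 median gave 79 and 161, 83 and 136, and 38 and 41. Leaving out the C57BL/6 male, C57BL/6 female, C3H/HeJ male or C3H/HeJ female control gave 100, 90, 80 and 77 genes between those strains. Leaving out the A/J male, A/J female, C57BL/6 male or C57BL/6 female control gave 65, 92, 87 and 70 between C57BL/6 and A/J, and leaving out the A/J male, A/J female, C3H/HeJ male or C3H/HeJ female control 34, 27, 37 and 32 between A/J and C3H/HeJ.

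The sex term, which also carries the dose in treated mice, called 3 genes: Xist (3.39 higher in females, SE 0.19, adjusted p = 1.4e-08), Eif2s3x (0.46, SE 0.06) and Uty (−1.28, SE 0.15), with 292 at an unadjusted p under 0.05. Xist ran from 6.63 to 8.73 on the 10 male and from 9.29 to 11.9 on the 11 female arrays, and the Y-linked Eif2s3y from 6.85 to 8.12 and from 4.02 to 4.58, so no array lay on the other sex's side. Xist was nevertheless higher in the male pools of C3H/HeJ at 3 weeks (8.73) and of A/J at 80 mg/kg (8.24) than in the other male pools, and some female RNA in these 2 was not ruled out. Without them 171 genes in place of 27 passed for the response of C57BL/6 against C3H/HeJ. The sex difference of the response gave 0 genes with limma and 216 at an unadjusted p under 0.05; Kank2 (−1.39, SE 0.33), Lce1a1 (−1.51, SE 0.40) and Atp8a1 (−0.83, SE 0.21) had the smallest p and did not pass.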

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

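The differences between groups below were planned. The tests of explanations, with array brightness, the Gapdh ratio, the muscle genes and the second probe sets, were chosen only after the data had been seen, and those of the muscle list against the endothelial and epithelial lists after its own result was seen.

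The response of C57BL/6 at 3 weeks differed from that of C3H/HeJ, by a test of the difference itself, in 20 named genes and 1 list. Higher were Pstpip2 (2.15), Gpnmb (1.94), Armcx4 (1.94), Ajuba (1.80), Hmox1 (1.78), Pdzrn3 (1.73), Apoe (1.72), Myc (1.70), Ltbp2 (1.61), C1qc (1.49) and Ccl9 (0.97). Lower were Hbb-b2 (−2.32), Pcolce2 (−1.81), Oas3 (−1.50), Dcn (−1.48), Pttg1 (−1.48), Slc7a10 (−1.40), Polr2a (−1.26), Klf5 (−1.25), Tppp3 (−1.05) and the median of the red cell list (−0.65). In control lungs Pttg1 was 2.53 higher in C57BL/6 than in C3H/HeJ. With the deposited scaling 18 of the 20 genes lost their call, and 16 did in some fit that left out an array.

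C57BL/6 differed from A/J, by the same test, in 50 named genes and 4 lists. Higher were Tnc (2.63), Cxcl10 (2.53), C1qb (2.21), Fst (2.19), Armcx4 (2.18), Msr1 (2.14), C1qc (2.08), Timp1 (2.01), Mcm2 (2.01, with its second probe set at 0.66), Mt2 (1.91), C1qa (1.88), Reg3g (1.71), Gpnmb (1.69), Fcgr1 (1.67), Ccl9 (1.63), Ltbp2 (1.54), Cfb (1.46), Irf7 (1.41), Ccl8 (1.40), Fmod (1.31), Ctss (1.25), Muc5b (1.25), Mmp14 (1.23), Cd68 (1.18), Ifit3 (1.17), Tgfbi (1.13), Anln (1.11), Ifit2 (1.09), Col5a2 (1.09), Cald1 (0.84), Mif (0.78), and the medians of the macrophage (0.59), protease (0.37) and complement (0.23) lists. Lower were Ngp (−2.06), Gjb6 (−1.93), Bex2 (−1.85), Cyp1a1 (−1.85), Pcolce2 (−1.75), Dpep1 (−1.73), Hbb-b2 (−1.73), Slc7a10 (−1.72), Etv5 (−1.39), Fmo1 (−1.15), Car4 (−1.12), Tppp3 (−1.12), Eng (−1.08, with its second probe set at −0.09), Ptprb (−1.01), Aox1 (−0.99), Bmp6 (−0.98), Gstm1 (−0.94), Limch1 (−0.75, with its second probe set at −0.24), Sftpa1 (−0.72) and the median of the red cell list (−0.62). A/J and C3H/HeJ differed in Oas3 (−1.79).

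In the A/J group at 3 weeks, the only group of 4 arrays, 1 array stood apart in 4 of the 54 genes looked at, in that its gap to the next took up most of the range of the 4 values, where chance gives 2.7. These were Ccl6 (log2 signal 11.3 in the female pool at 100 mg/kg), Cdkn1a (10.4) and Col3a1 (11.2) in the female pool at 125 mg/kg, and Ifi202b (7.63) in the male pool at 100 mg/kg. Such a gap is narrow where the other arrays lie close, as in Ccl6, whose changes from the control of the same sex ran only from 0.82 to 0.99. Among the 1223 probe sets without exactly 1 gene symbol, which the comparisons of genes did not use, 165 passed in the mean of the 3 strains at 3 weeks, 80 higher and 85 lower.

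More genes passed at 3 weeks in C57BL/6 than in the other strains, 1186 against 257 in C3H/HeJ, a ratio of 4.61 to the larger of the other counts, which ran from 1.83 without the C57BL/6 male 3 week array to 12.1 without either C3H/HeJ control. If array brightness were the whole cause the ratio should have dropped to 1.5 or less with brightness as a covariate. It was 4.13, so a linear trend with brightness left after normalization did not account for the ratio. Quantile normalization had already brought the arrays to 1 level, though. A covariate for the mean also cannot show whether dim arrays were noisier. The test therefore does not decide on brightness. With the Gapdh ratio, a measure of RNA quality, as a covariate the ratio of counts was 5.67. Within groups the Gapdh ratio differed most between the C3H/HeJ 6 week arrays (1.07 and 2.08), which are not part of these counts. This covariate therefore does not decide on RNA quality. A difference between strains in the response may underlie the counts but stays untested as their cause, as do drug uptake and the mice pooled. Over all 9079 genes the median absolute change was 0.24 in C57BL/6 and 0.20 in C3H/HeJ at the same median SE (0.198). The model pools the variance over groups, so this SE is equal by construction. Simulated 2-fold changes were recovered to 76% and 79%, but the simulation gave every array of a gene the same spread. Whether power favoured C57BL/6 was therefore not tested. Estimated array weights were 1.27 for each C57BL/6 and 0.589 for each C3H/HeJ 3 week array, which leaves a difference in precision open. The test of the difference recovered 26.5% of 2-fold and 96.5% of 4-fold differences between these strains, and the genes it called include some, such as Oas3, that rose less in C57BL/6.

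The median of the heart and skeletal muscle genes was lower at 3 weeks in every strain, although in C3H/HeJ the list did not pass with an estimated correlation (adjusted p = 0.127). Dilution by cells that enter the lung should lower resident genes alike, but the muscle list fell by more (mean −0.63 over 26 genes) than the pooled endothelial and epithelial lists (−0.12 over 117 genes; permutation p = 1e-05, the smallest the resampling can give, with genes treated as independent). With arrays as the unit the real labels gave the largest difference of all 540 labelings within strain (exact p = 0.00185, the smallest possible). However, the muscle list had been picked for its fall, and the lists set against it also hold genes that rose, such as Eln and Retnla. Neither test therefore decides whether dilution was the cause. Uneven carry-over of heart tissue at dissection stays open: in 3 of 3 strains every 3 week array lay below both controls, but this restates that fall, and in C3H/HeJ the male 3 week array (0.09) lay close to the male control (0.24). The A/J controls, from which the A/J falls were measured, had the highest list levels of all arrays (0.65 in males and 0.46 in females). Dilution, carry-over, uneven or systematic, and a real loss of muscle transcripts, such as those of the heart muscle sleeve of the pulmonary veins, may each contribute to the fall.

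Genes that differed between strains in control lungs may in part reflect a sequence variant under a probe set. Of the called genes with a second probe set, the second followed in 44.6% over the 3 comparisons, which share arrays and genes, against 67.8% at 3 weeks in C57BL/6, where no variant separates the groups. Taken singly, the shares were 44.8% between C57BL/6 and C3H/HeJ (Fisher's exact p = 7.6e-05), 43.2% between C57BL/6 and A/J (p = 3.0e-06) and 48.5% between A/J and C3H/HeJ (p = 0.0338). This is what variants under probes would give, although a gene whose transcripts differ in form between strains would give it too, and the share that a variant explains gene by gene was not measured. Of the histocompatibility genes between C57BL/6 and C3H/HeJ, the second probe set of H2-D1 followed (3.58 beside 3.41) and that of H2-K1 did not (0.33 beside 2.26).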

How the results depend on the processing

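Scaling to 1 median, brightness and the Gapdh ratio as covariates, and the fits without the C3H/HeJ female 6 week array or without the 2 male arrays with the highest Xist were chosen after the data were seen; the other alternatives were planned. The values below are counts of called genes unless named otherwise. For those that moved by more than 1.5 times the cause was not tested, except where the construction of the alternative shows it.

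Over all alternatives the values of single named genes stayed on their side of the threshold in 22563 cases, fell short of it in 1188, newly passed it in 403 and reversed in 3. The 22563 cases include genes that passed in neither setting, with or without a change of sign. They therefore do not measure how often called genes kept their call. Of the 1188 cases 148 were with the deposited scaling. The reversed values were those of Cald1 (−0.0291), Ier5 (−0.0143) and Tapbp (−0.0526) in the mean of the strains with the deposited scaling. The lists called in the comparisons whose list members are named were tested again under the settings that refit all groups and by the 2 other list tests, but not with 1 array left out in turn. There they kept their call in 1421 cases and lost it in 161, of which 69 were with an estimated correlation and 31 with fry, and 0 reversed in direction. Medians of some lists turned with the deposited scaling, where the median of all genes had itself shifted. Over all comparisons, others included, 168 list calls stood beside 54 with an estimated correlation and 107 with fry, which test other hypotheses or allow more correlation by construction.

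The deposited scaling gave 387 genes in C57BL/6 and 86 in C3H/HeJ at 3 weeks, 701 in moribund mice, 2 in moribund against 3 weeks and 6 in A/J at 6 weeks. It gave 2, 25 and 0 for the response of C57BL/6 against C3H/HeJ, of C57BL/6 against A/J and of A/J against C3H/HeJ, 95, 132 and 32 for the same pairs in control lungs, and 18 genes shared by C57BL/6 and C3H/HeJ. The share of genes called at 3 weeks that lay on the same side in the C57BL/6 pool at 6 weeks was 92.7% there and 93.6% with scaling to 1 median. The larger spread between unscaled arrays is part of that construction. Scaling to 1 median gave 59 for C57BL/6 against C3H/HeJ. An offset of 1 gave 2 in moribund against 3 weeks, an offset of 64 gave 0 for A/J against C3H/HeJ and 5 for the sex term, and no dim filter gave 5 for the sex term.

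Array weights gave 227 in A/J and 1845 in C57BL/6 at 3 weeks, and 17 in A/J at 6 weeks. They gave 132 and 462 for the responses of C57BL/6 against C3H/HeJ and A/J, and 713, 758 and 194 in control lungs. Every probe set tested gave 1 in moribund against 3 weeks, 0 for A/J against C3H/HeJ, 377, 478 and 152 in control lungs and 8 for the sex term, and it counts probe sets. An adjusted p under 0.10, which passes more by construction, gave 164 in A/J and 425 in C3H/HeJ at 3 weeks, and 10 in moribund against 3 weeks. It gave 167 and 314 for the responses of C57BL/6 against C3H/HeJ and A/J, 425 and 445 for the same pairs in control lungs and 1 for the A/J dose. Only the arrays of the strains compared, with fewer degrees of freedom, gave 454 in C57BL/6 and 125 in C3H/HeJ at 3 weeks, 528 in moribund mice, 1 in C3H/HeJ at 6 weeks, and 4 for the response and 104 for control lungs of C57BL/6 against C3H/HeJ.

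Brightness as a covariate gave 3 in moribund against 3 weeks, 56 for the response of C57BL/6 against C3H/HeJ and 0 for A/J against C3H/HeJ. The Gapdh ratio gave 11, 40 and 0 for the 3 responses, 106 for control lungs of C57BL/6 against A/J and 1 for the A/J dose. Without the C3H/HeJ female 6 week array 3 genes passed in moribund against 3 weeks, 6 in C3H/HeJ at 6 weeks, 0 for A/J against C3H/HeJ and 1 for the A/J dose. Without the 2 male arrays 3 passed in moribund against 3 weeks, 171 for C57BL/6 against C3H/HeJ, 5 for A/J against C3H/HeJ, 2 for the A/J dose, and 67 were shared by C57BL/6 and C3H/HeJ.

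Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 27 to 88 genes in A/J, 427 to 831 in C57BL/6 and 68 to 221 in C3H/HeJ at 3 weeks. It gave 1014 to 1481 in the mean of the strains, 669 to 1546 in moribund mice, 1 to 52 in moribund against 3 weeks, 3 to 11 in A/J and 6 to 14 in C3H/HeJ at 6 weeks. It gave 5 to 184 for the response of C57BL/6 against C3H/HeJ, 17 to 182 against A/J and 0 to 3 for A/J against C3H/HeJ. In control lungs it gave 77 to 100, 65 to 92 and 27 to 37 for the same pairs, 45 to 92 shared genes, 3 to 4 for the sex term, 0 to 2 for the A/J dose and 0 for the sex difference of the response. For these ranges only the arrays of the groups compared were left out, and fits without other arrays went beyond some of them. Loss of an array lowers power by construction, so the low ends are partly that.

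Under the other settings, namely no sex term, the lower 50 percent of probe sets left out and A/J arrays at the doses of the other strains, every count stayed within 1.5 times of its main value. Signal over background limits what can be said of the dimmest 33.3 percent of the probe sets, which were left out, and of Scgb1a1 and Sftpc at the top of the scale.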

Other observations

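The splits below were planned. The 14 arrays at 3 weeks and in control lungs were divided at random within strain into groups of the same sizes. Only 1 of 100 splits, the real one, gave as many genes as the real 1541 in the mean of the strains. This is the smallest share that 100 splits can give, so chance is unlikely for that count but not excluded. The highest other split gave 1009; it gave 12 of the 14 arrays the opposite label, close to a mirror image of the real split, and the median of the other splits was 0. For the sex term 1 of 100 splits within groups, the real one, gave as many as the 3 genes, and the highest other gave 1. Chance is again unlikely but not excluded by 100 splits. For the sex difference of the response the real count was 0, so all 100 of 100 splits gave as many by construction and the splits decide nothing; the highest other gave 1.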
